A study of Homo sapiens with 4 samples.

How the data were processed

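Total RNA, extracted with Trizol per the labels' protocols, was sequenced from 4 PC9 libraries prepared with a TruSeq kit. The deposited values are FPKM per gene symbol, 1 file per library with 26485 rows. The submitters' processing notes list FastQC 0.11.8, STAR 2.6.1b, featureCounts 1.6.3 and DESeq2 1.22.2 with the human build GRCh38, without saying which step each performed; the program that computed FPKM and the gene annotation are not given in the sources used here. Whether counting used strand is not given either, so reads of overlapping antisense genes may have been counted together. Symbols were matched to GENCODE release 29 (GRCh38) for coordinates, transcript length (the median over a gene's transcripts) and GC content: 23873 matched directly, 26 through an older symbol and 2586 not at all. In each library 104 rows, mostly near-identical gene copies, held no value, and 28 symbols had been turned into dates by a spreadsheet; 18 of these were tested but none is named.

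The analysis planned before the data were examined assumed counts. The files hold FPKM whose low values are not whole multiples of 1 fragment, so a count model was not used and the main test was changed to limma 3.58.1 in R 4.3.3 on log2(FPKM + 1). Genes with a mean of at least 1 FPKM over the 4 libraries were kept (11328), the variance prior followed the mean level, and p-values were two-sided with Benjamini-Hochberg adjustment. The prior had 5.21 degrees of freedom and the residual 2. Groups were DTP (replicates 1 and 3) against parental (replicates 2 and 3), with no covariate. The median SD between replicates was 0.07 on the log2 scale. The FPKM summed to 410898 and 426440 in the parental and 347545 and 361449 in the DTP libraries.

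Depth was estimated from genes with 1 annotated transcript. The median of their FPKM times length inside a fixed window of low values was taken as the value of 1 fragment. The window limits what the estimate can be, and whether values clustered there was not tested. The median in a second fixed window lay at 1.77 to 1.82 times the first, not at a whole multiple, so the estimate is rough. On this estimate a gene of 1 FPKM and 1 kb rests on 18.7 to 20.8 fragments. The test was tried on simulated data for the comparison of DTP with parental: 5 runs over 11328 genes with 200 changed. It recovered 1.6% of log2 changes of 0.25, 43.2% of changes of 0.5, 93.2% of changes of 1 and 100% of changes of 2. Among the calls 2.9% were false. In the data 75.6% of tested genes passed, so the adjusted threshold was stricter in the simulation. Its noise was also drawn separately for each gene, without shifts shared by a library. These rates therefore do not carry over to the comparison itself.

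Of 35 gene lists fixed before the data were examined, the 31 with at least 3 tested members were tested with camera at a preset correlation of 0.01, with an estimated correlation and fry as alternatives. Named genes followed a rule fixed at the same time: the 10 largest rises and 10 largest falls among genes with an adjusted p under 0.05, an average log2 value of at least 3 and non-overlapping groups; 9 genes chosen in advance (EGFR, MET, AXL, ERBB3, DUSP6, MKI67, CDKN1A, KDM5A and GAPDH); and up to 4 members of each list, 2 per direction by smallest p. The level limit had been set for CPM and was applied to log2(FPKM + 1). Symbols of uncharacterised and small RNA genes were passed over, and a few genes that the rule names are not reported here. Genes of the region results and of the closing families were chosen after their values were seen.

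Alternatives were another pseudocount, other filters, other scalings, another threshold, a test against 1.5-fold, no variance trend, removal of a trend on length and GC, and leaving out each library in turn. The table of the whole series repeats the values of the single files and was not used.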

Results

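RNA was sequenced from PC9 cells, a human non-small cell lung cancer line that carries an activating EGFR mutation. Parental cells had been kept in the solvent DMSO for 9 days, and drug-tolerant persister (DTP) cells had survived 9 days in 2 µM osimertinib, an inhibitor of mutant EGFR. There were 4 libraries, parental replicates 2 and 3 and DTP replicates 1 and 3, which the labels describe as biological replicates. The values were FPKM, fragments scaled to transcript length and to the number of mapped fragments. Depth was not given. A rough estimate was read from a fixed window of low values, which limits what it can be. The estimate came to about 20800000 and 18700000 fragments for the parental and 20800000 and 20100000 for the DTP libraries. Between 15965 and 16408 genes were above 0 in a library. Across the 11328 genes tested, log2(FPKM + 1) correlated at r = 0.996 between the parental libraries and 0.994 between the DTP libraries, against 0.872 to 0.878 across the groups; genes are not independent replicates.

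The comparison asked how the transcriptome of cells that survived osimertinib differs from that of the untreated line. No other treated or drug-released cells were among the libraries. Effects of the drug itself, of selection of survivors and of tolerance therefore cannot be told apart. DTP cells had lower transcripts of the ERK pathway's output genes, of the cell cycle and of ribosome biogenesis, and higher transcripts of lysosome and autophagy genes, of a joint list of CDK inhibitors and FOXO-linked genes, and of interferon-response genes. These are changes of fixed gene lists, of which 12 of 31 were called with a preset correlation between genes and 0 with an estimated one. The test with an estimated correlation rests on only 2 residual degrees of freedom here. Of the 11328 genes, 3913 were higher and 4646 lower in DTP (limma, two-sided, Benjamini-Hochberg adjusted p under 0.05). With a change of at least 2-fold as an added limit, 1024 were higher and 1142 lower. Fold changes are on the scale of log2(FPKM + 1), which understates the change of genes with low values. The split depended on scale: with every library brought to the same total (TPM scale), 5238 genes were higher and 3365 lower (1435 and 787 at 2-fold), and the median change of all genes moved from -0.06 to 0.15. In 9998 genes (88.3%) the groups did not overlap, where chance gives 33.3% for a single gene. All genes share the same 4 libraries, so a shift of whole libraries would separate many genes at once. The share is therefore not a test. With 2 libraries per group an exact permutation test of a single gene cannot go below p = 0.333, so the gene-wise calls rest on limma's shared variance.

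Among genes of at least moderate level, the largest rise was that of ALPP, placental alkaline phosphatase (chromosome 2, 232378534 to 232382889, GRCh38). It stood at 26.8 ± 0.836 FPKM (SD, n = 2) in parental and 1570 ± 115 in DTP cells (log2 change 5.82, SE 0.07). SOD3, the extracellular superoxide dismutase, went from 4.19 ± 0.410 to 212 ± 2.78 FPKM, and ATP6V1B1, a subunit of the vacuolar proton pump, from 1.37 ± 0.389 to 70.8 ± 3.08. Transcripts of the insulin-like growth factor binding proteins IGFBP5 (2.09 ± 0.338 to 75.6 ± 7.10) and IGFBP3 (21.2 ± 1.14 to 489 ± 1.40) rose, as did the surface glycoprotein gene CD24 (17.7 ± 1.13 to 412 ± 5.28). The same rule named UPK2, a urothelial plaque protein (log2 change 4.45), PSG5, a pregnancy-specific glycoprotein (4.36), the homeobox gene IRX6 (4.08) and the keratin gene KRT16 (4.04). ALPP, PSG5 and KRT16 have close paralogs, and their values are uncertain to the extent that reads were shared with them.

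The largest falls among these genes were those of MT2A, a metal-binding metallothionein (chromosome 16, 56608199 to 56609497), from 1605 ± 154 to 32.1 ± 1.95 FPKM (log2 change -5.60, SE 0.08), and CCND1, which encodes cyclin D1 (chromosome 11, 69641087 to 69654474), from 154 ± 3.05 to 4.99 ± 0.195 (-4.69, SE 0.05). The metallothionein MT1X (-4.46), whose sequence is close to that of its neighbours, the deiodinase DIO2 (-3.76), the chloride channel ANO1 (-3.49), the calpain CAPN8 (-3.18) and TFPI2, a serine protease inhibitor (-3.10), also fell. PRSS3, a trypsinogen with close paralogs (-3.02), RRM2, a subunit of ribonucleotide reductase (-3.00), and the adhesion gene AMIGO2 (-2.94) completed the list. Adjusted p-values of these 20 genes lay between 1.393e-08 and 9.808e-07.

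**Figure D1:**
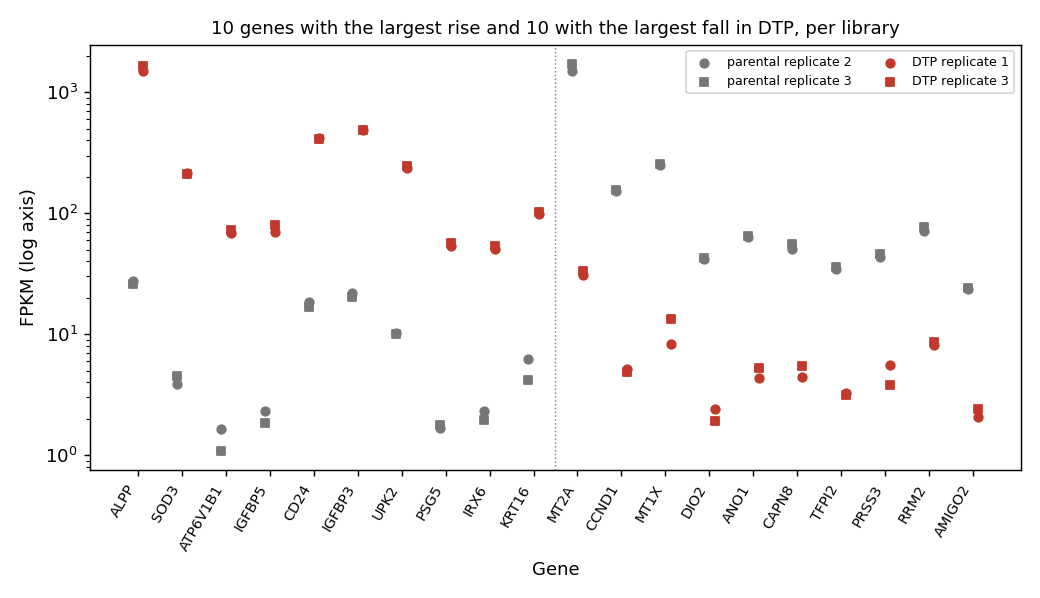
FPKM on a log axis for the 10 genes with the largest rise (left) and the 10 with the largest fall (right) among genes with an average log2(FPKM + 1) of at least 3, 1 point per library, grey for parental and red for DTP, with circles and squares for the replicates. The rule took only genes with an adjusted p under 0.05 in which both DTP libraries lie on the same side of both parental libraries. That separation is therefore not a result. ALPP stands at 26.8 in parental and 1570 in DTP on average.

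ERK pathway output genes, which report signalling downstream of EGFR, were lower in 14 of 17 tested members and higher in 2, with a median log2 change of -2.83 (camera with a preset correlation of 0.01, adjusted p = 0.000122; adjusted p = 0.465 with an estimated correlation). The phosphatase genes DUSP6 (11.7 ± 0.352 to 0.219 ± 0.0248 FPKM) and DUSP4 (34.7 ± 0.684 to 0.763 ± 0.134) fell, while DUSP5 (8.45 ± 0.195 to 14.2 ± 0.624) and the ephrin receptor gene EPHA4 (5.29 ± 0.0271 to 9.79 ± 0.395) rose. EGFR itself stood at 94.4 ± 5.51 FPKM in parental and 94.4 ± 3.66 in DTP cells (adjusted p = 0.999). On the TPM scale its log2 change was 0.24 (adjusted p = 0.00322), and without the 10 most abundant genes 0.21 (adjusted p = 0.00645). Of 11 tested receptor tyrosine kinases, 6 were higher and 3 lower, and the list did not pass the test (adjusted p = 0.457). ERBB3 rose from 15.6 ± 0.591 to 47.7 ± 2.32 FPKM and ERBB2 from 15.6 ± 0.520 to 32.1 ± 1.00, whereas MET fell from 16.8 ± 0.584 to 6.02 ± 0.193 and AXL from 4.37 ± 0.601 to 0.618 ± 0.167. Among ligands and growth factors 1 was higher, BTC (log2 change 1.10), and 7 lower, including IGF2 (-1.95) and AREG (-1.42), without a call for the list (adjusted p = 0.266).

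All 22 tested G2/M genes were lower in DTP (median log2 change -2.28, camera adjusted p = 8.96e-10; adjusted p = 0.484 with an estimated correlation). Of 27 genes of DNA replication 26 were lower (median -1.51, camera adjusted p = 4.09e-09; adjusted p = 0.484 with an estimated correlation). The mitotic kinase genes PLK1 (114 ± 1.00 to 17.6 ± 0.0388 FPKM) and AURKA (94.1 ± 2.13 to 15.2 ± 0.144) fell, as did MKI67, a marker of cycling cells (32.9 ± 1.02 to 6.72 ± 0.582), and TYMS, thymidylate synthase (43.1 ± 0.108 to 9.26 ± 0.0269). CDK inhibitors and FOXO-linked genes were higher in 14 of 15 tested members (median 1.14, camera adjusted p = 5.51e-06; adjusted p = 0.465 with an estimated correlation). The transcriptional repressor BCL6 (log2 change 2.10) and the antiproliferative gene BTG1 (1.75) rose with the smallest p in the list, and CDKN1A (p21) rose from 5.64 ± 0.324 to 7.19 ± 0.0949 FPKM. All 20 tested genes of ribosome biogenesis were lower (median -1.41, camera adjusted p = 3.3e-07; adjusted p = 0.484 with an estimated correlation), among them BOP1 (-2.43) and NOLC1 (-1.83).

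Lysosome and autophagy genes were higher in 23 of 31 tested members and lower in 1 (median log2 change 0.67, camera adjusted p = 1.21e-06; adjusted p = 0.465 with an estimated correlation). ASAH1, acid ceramidase, rose from 33.7 ± 0.575 to 157 ± 1.31 FPKM and the cathepsin gene CTSF from 9.51 ± 0.342 to 56.5 ± 3.51, while GLA fell from 22.9 ± 0.501 to 14.5 ± 0.260. Cholesterol synthesis genes were higher in 17 of 23 and lower in 3 (median 0.44, camera adjusted p = 0.0021; adjusted p = 0.518 with an estimated correlation). TM7SF2 (2.45) and HMGCS1 (1.46) rose, and PMVK (-0.40) fell. Glycolysis genes were lower in 15 of 18 and higher in 2 (median -0.65, camera adjusted p = 0.0021; adjusted p = 0.518 with an estimated correlation). PFKP (-2.04) and TPI1 (-1.28) fell, and GAPDH, often used as a reference gene, fell from 4425 ± 79.4 to 2821 ± 150 FPKM. The calls of the 2 glycolysis genes that rose did not survive every alternative. SLC16A1 had an adjusted p of 0.137 without parental replicate 2, 0.0886 without parental replicate 3, 0.0816 without DTP replicate 3 and 0.056 without a variance trend. PFKFB3 had 0.0665 without parental replicate 3 and 0.167 after removal of a length and GC trend. Nuclear-encoded oxidative phosphorylation genes were lower in 19 of 21 (median -0.64, camera adjusted p = 0.000275; adjusted p = 0.518 with an estimated correlation), such as CYCS, cytochrome c (-1.55), and NDUFS3 (-0.92).

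Interferon-response genes were higher in 13 of 17 tested members and lower in 2 (median log2 change 0.86, camera adjusted p = 0.000698; adjusted p = 0.484 with an estimated correlation). IFITM1, which has close paralogs (2.98 ± 0.0971 to 55.6 ± 1.68 FPKM), and IFI6 (7.53 ± 0.739 to 86.2 ± 5.28) rose, while OAS3 (-1.10) and USP18 (-0.84) fell. YAP/TEAD target genes were higher in 13 of 20 and lower in 6 (median 0.56, camera adjusted p = 0.032; adjusted p = 0.484 with an estimated correlation), with IGFBP3 and CRIM1 (1.86) among those that rose and FJX1 (-1.95) and AXL among those that fell. That call was lost with a higher median on the TPM scale (median 0.78, adjusted p = 0.0689) and without the 10 most abundant genes (0.76 and 0.065). It was lost with a lower median without a filter (0.28 and 0.103) and with a filter of 1 FPKM in 2 libraries (0.35 and 0.0749). Over the 12 alternatives of scaling, filter, pseudocount, trend and left-out library the adjusted p ran from 0.0256 to 0.103. The p53 target genes were higher in 12 of 17 and lower in 2 (median 0.64, camera adjusted p = 0.013; adjusted p = 0.484 with an estimated correlation), a call lost without a filter on low values (adjusted p = 0.0526, range over alternatives 0.00972 to 0.0526). TP53INP1 (2.32) and SESN1 (1.38) rose, and AEN (-1.75) and DDB2 (-0.88) fell.

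**Figure D2:**
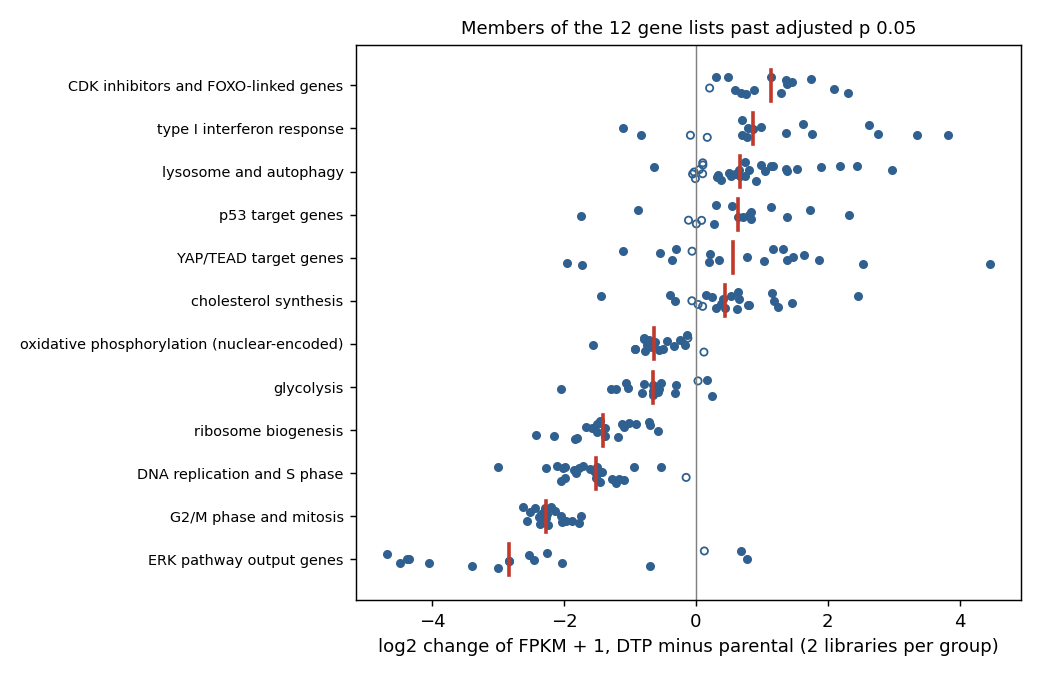
Log2 change of FPKM + 1, DTP minus parental, for each tested member of the 12 lists with an adjusted p under 0.05. Filled points are genes past an adjusted p of 0.05, open points are not, and the red line is the list's median; the medians run from -2.83 for ERK pathway output genes to 1.14 for CDK inhibitors and FOXO-linked genes.

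The other lists did not pass the test, though most held genes that changed in opposite directions. Of 19 epithelial genes 11 were higher and 5 lower (adjusted p = 0.0875). The claudin genes CLDN3 (2.16) and CLDN4 (1.40) rose, and the keratin genes KRT7 (-1.70) and KRT18 (-1.33) fell. Of 8 mesenchymal genes 3 were higher, among them S100A4 (1.28) and COL6A1 (0.47), and 2 lower, TAGLN (-0.51) and CDH2 (-0.30). The median was -0.05, the mean 0.17 and the direction of camera upward (adjusted p = 0.566). The CDH2 call was lost under 11 of 15 alternatives, with a log2 change of -0.18 on the TPM scale (adjusted p = 0.229) and -0.33 without parental replicate 2 (adjusted p = 0.0853). In the airway secretory list 5 genes were higher and 3 lower, with a median of 0.70, a mean of -0.28 and an adjusted p of 0.356. The mucin genes MUC1 (6.66 ± 0.528 to 71.7 ± 1.35 FPKM) and MUC16 (7.77 ± 0.620 to 23.8 ± 0.119) rose, and CEACAM6 (-2.53) fell. TFF1 also fell, from 16.5 and 24.1 FPKM in the parental libraries to 0.222 and 0 in the DTP libraries. Alveolar type 1 genes split into 4 higher and 5 lower (adjusted p = 0.755), with GPRC5A (1.00) and CLIC5 (2.17) up and CAV1 (-1.98) and IGFBP2 (-1.57) down. Of 3 alveolar type 2 genes ETV5 (-3.00) and ABCA3 (-0.33) fell (list adjusted p = 0.354), although the ABCA3 call was lost on the TPM scale (adjusted p = 0.149) and without the 10 most abundant genes (0.0927). The 3 tested neuroendocrine genes fell, such as UCHL1 (-1.23) and STMN1 (-1.17), with an adjusted p of 0.0583 for the list. That list passed under 5 of the 12 alternatives, with an adjusted p from 0.0295 (TPM scale) to 0.298 (no filter) over them.

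NF-kappaB target genes were higher in 4 and lower in 4 of 10 (adjusted p = 0.527). ICAM1 (2.96) and NFKB2 (1.98) rose, and LIF (-1.90) and TNFAIP3 (-1.16) fell. The BCL2 family had 7 higher and 4 lower of 15 (adjusted p = 0.342), with the pro-apoptotic genes BCL2L11 (4.68 ± 0.623 to 23.5 ± 0.552 FPKM) and PMAIP1 (1.04) up and BIK (-1.03) and BAD (-0.47) down. Integrins and laminins had 7 higher and 10 lower of 18 (adjusted p = 0.354), with LAMB2 (1.98) and LAMB3 (0.81) up and ITGA2 (-3.29) and ITGA6 (-1.94) down. Genes named earlier for persister cells had 7 higher and 5 lower of 14 (adjusted p = 0.354). Beside CD24 and IGFBP3, KDM5A, a histone demethylase, rose from 4.32 ± 0.0839 to 6.06 ± 0.112 FPKM, and CD44 fell from 135 ± 5.87 to 46.6 ± 1.95. NOTCH1 (1.78) and NOTCH2 (0.99) rose while NRARP (-1.30) and JAG1 (-1.18) fell, and in the WNT and Notch list 2 genes were higher and 6 lower of 9 (adjusted p = 0.457). NRF2 targets had 7 higher, such as GCLC (1.19), and 11 lower, such as GPX2 (-1.29), of 19 (adjusted p = 0.617). ATF4 targets had 6 higher, such as VLDLR (1.95), and 9 lower, such as the serine synthesis gene PSAT1 (-2.49), of 16 (adjusted p = 0.511). Fatty acid oxidation genes had 7 higher, such as ACSL1 (0.64), and 10 lower, such as ETFB (-1.31), of 18 (adjusted p = 0.755). Hypoxia genes had 6 higher, such as NDRG1 (2.79), and 3 lower, such as CA9 (-1.66) and PDK1 (-0.69), of 12 (adjusted p = 0.354). Immediate early and heat shock genes had 3 higher, such as ATF3 (1.43), and 7 lower, such as EGR1 (-2.45) and HSPA8 (-1.61), of 10 (adjusted p = 0.347).

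In the lists above, the counts adjusted over the list alone were the same as those over all genes except in 3 lists: mesenchymal genes (3 higher and 1 lower), oxidative phosphorylation (1 higher and 19 lower) and NRF2 targets (8 higher and 11 lower). Over the 12 alternatives the medians of called lists ran, for example, from -4.27 to -2.64 (ERK pathway output), 0.39 to 1.31 (interferon response), 0.37 to 0.67 (cholesterol synthesis), -0.70 to -0.41 (glycolysis) and -0.67 to -0.40 (oxidative phosphorylation). The lowest interferon median came without a filter, and the smallest falls of the last pair on the TPM scale. None of the 12 list calls held with an estimated correlation, which has only 2 residual degrees of freedom here. With it, 3 lists had an unadjusted p under 0.05. For ERK pathway output (-0.015) and lysosome and autophagy genes (0.0076) the estimated correlation was not above the preset 0.01. The loss of these calls therefore does not show correlation among their members. For other lists, such as G2/M genes (0.445), the estimate was well above it.

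Antigen presentation could not be read fully. Of 169 protein-coding genes between 28503296 and 33457548 on chromosome 6 (GRCh38), the major histocompatibility region, 160 (94.7%) were below 0.5 FPKM in all 4 libraries, and 115 were listed at 0 in all. Genes that cells use throughout were among them: TUBB was listed between 0 and 0.0663 FPKM and RPS18 between 0 and 0.160, and CLIC1, LSM2 and ABCF1 were listed at 0 in every library. In the flanking 5 Mb, 39% of 100 genes on the lower side and 32.8% of 61 on the upper side were below 0.5. Values of 0 there can be failed estimates. Of the 16 genes of class I antigen presentation 10 lie in the region; 8 were tested, 5 were higher and 1 lower (adjusted p = 0.252), with ERAP1 (0.86) and PSMB10 (0.33) up and NLRC5 (-0.45) down. None of the 11 class II genes, 9 of them in the region, reached the level tested.

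**Figure D3:**
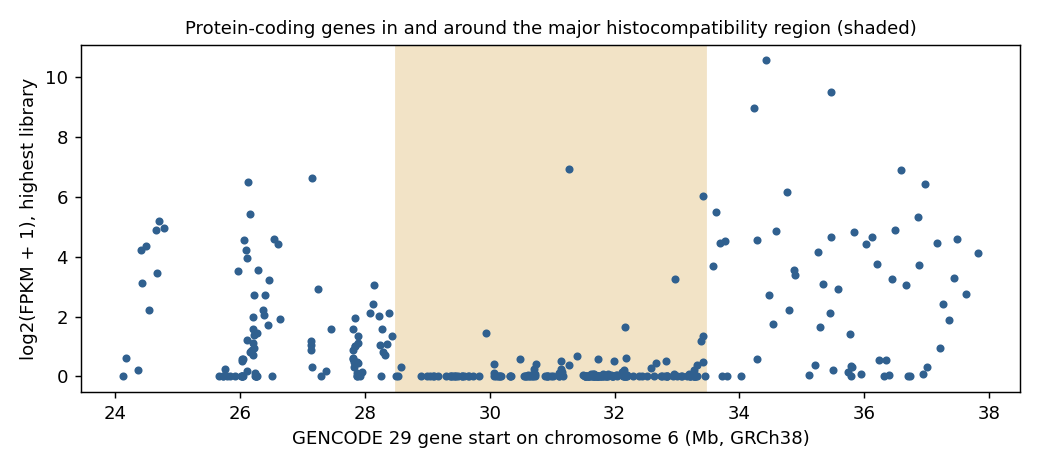
Highest log2(FPKM + 1) of the 4 libraries for each protein-coding gene against its start on chromosome 6 in Mb (GRCh38), with the major histocompatibility region shaded. Of the 169 genes in the shaded region, 160 are below 0.5 FPKM in all libraries.

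Markers of other cell types were low. The mean of 11 leukocyte markers was 3.11 and 3.33 FPKM in the parental and 1.15 and 1.2 in the DTP libraries, most of it from CD68 (33.5 ± 1.63 to 11.2 ± 0.0291 FPKM). CD14 stood at 1.07 ± 0.0325 and 1.16 ± 0.309 (adjusted p = 0.704). Stromal markers averaged 0.0709 and 0.0683 FPKM in parental and 0.175 and 0.153 in DTP libraries, with COL1A1 the only one tested (0.610 ± 0.0484 to 1.55 ± 0.121). Endothelial markers averaged 0.199 and 0.179 FPKM in parental and 0.127 and 0.0832 in DTP libraries.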

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

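The scalings of FPKM, the filter of 1 FPKM in 2 libraries, the test against 1.5-fold, the fit without a variance trend and the removal of a length and GC trend were chosen after seeing the data. The planned count models and their normalizations and filters were not run because the files hold no counts. No paired analysis was possible because the groups share only 1 replicate number. Against 1.5-fold, 3128 genes passed, 1427 higher and 1701 lower, in place of 8559, 3913 and 4646; this asks for a larger change by construction. Without each library in turn 7677 to 8155 genes passed, the lone library being assumed to vary like the other group. Of the lists, 0 passed with camera and an estimated correlation (3 at an unadjusted p under 0.05) and 29 with fry, which does not compare a list with other genes; 10 of the 12 called lists kept their call under every pseudocount, filter, scaling, trend removal and left-out library. On the TPM scale 60.9% of calls were higher in DTP, and without the 10 most abundant genes 59.2%, against 45.7%; the median of all genes was 0.15 and 0.13 there, against -0.06. Of 131 genes followed under the naming rule, some of them not printed in the report, 103 kept direction and side of the threshold throughout, and 19 more lost only the test against 1.5-fold. SDHA (0.12, not called in the main test) was called higher under 6 of 15 alternatives, with 0.361 on the TPM scale.

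Of the reported results these changed direction, none of them called in the main test; the cause was not tested. EGFR (0.00) ranged from -0.059 to 0.059 without each library in turn, and stood at -0.003 with median-of-ratios scaling and -0.046 after trend removal, but it was called higher on the TPM scale (0.238) and without the 10 most abundant genes (0.212). GAS6 (0.15) stood at -0.041 after trend removal, but it was called higher on the TPM scale (0.369), without the 10 most abundant genes (0.346), without DTP replicate 1 (0.246) and with upper-quartile scaling (0.227). Without each library in turn, LPCAT1 (0.07) ranged from -0.075 to 0.21 and CD14 (0.06) from -0.091 to 0.201. Without a filter camera's direction turned for mesenchymal genes (median -0.033) and alveolar type 2 genes (median 0.034). Mean FPKM of leukocyte markers moved to 2.99 (parental) and 1.28 (DTP) without the 10 most abundant genes and to 2.96 and 1.29 on the TPM scale. Stromal markers in parental cells moved to 0.0647, 0.0641 and, with upper-quartile scaling, 0.0677, and endothelial markers in parental cells to 0.174 on the TPM scale; the cause is the scaling itself. Without each library in turn these means ranged from 3.11 to 3.33 and 1.15 to 1.2 (leukocyte), 0.0683 to 0.0709 and 0.153 to 0.175 (stromal), and 0.179 to 0.199 and 0.0832 to 0.127 (endothelial).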

Other observations

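The families here were taken from 23 scanned by symbol after the values were seen. Clustered histone genes were higher in DTP in 14 of 17 tested members and lower in 0 (limma, adjusted p under 0.05). Their median log2 change was 1.40 (1.55 on the TPM scale). Several passed the filter only through their DTP values, such as HIST1H2AK (mean 0.288 FPKM in parental, 2.56 in DTP) and HIST1H2BF (0.171 and 2.61). Many other histone genes were too low to test, such as HIST1H1B (at most 0.0873 FPKM) and HIST1H4A (0), so the count does not describe the whole family. HIST1H2AC stood at 9.27 ± 0.627 FPKM (SD, n = 2) in parental and 87.2 ± 3.14 in DTP cells, HIST1H2BD at 5.05 ± 1.23 and 42.1 ± 0.098, and HIST1H1C at 6.08 ± 0.276 and 21.8 ± 0.763. Histone genes have close copies, so single values are uncertain. All 4 tested complement genes were higher, with C1R (2.81 ± 0.177 to 30.0 ± 1.95 FPKM) and C1S (3.15 ± 0.204 to 32.6 ± 1.63). The complement genes C2, C4A, C4B and CFB lie in the major histocompatibility region, were below 0.5 FPKM in all libraries and could not be tested. Of 11 semaphorin genes 9 were higher and 1 lower, with SEMA5A at 1.99 ± 0.11 and 25.0 ± 2.12 FPKM.

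All 8 genes of the CCT chaperonin, which folds actin and tubulin, were lower (median -1.16, and -0.92 on the TPM scale), as were 33 of 34 proteasome subunits (median -0.75, and -0.51 on the TPM scale) and 70 of 75 mitochondrial ribosomal proteins (median -0.76, and -0.53 on the TPM scale). Cytosolic ribosomal proteins had 45 of 79 lower and 4 higher, with a median of -0.26 that was -0.02 on the TPM scale. Of 5 tested insulin-like growth factor binding proteins IGFBP3 and IGFBP5 rose, and IGFBP4 (log2 change -2.11), IGFBP2 and IGFBP6 fell. The signal recognition particle RNA gene RN7SL2 differed between the DTP libraries, 2397 against 4434 FPKM, with 10630 and 10710 in the parental libraries.

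Of the tests below, the count of measured genes in the inner major histocompatibility region was chosen after the result was seen. The near-absence of that region could come from the genome of the cell line, but 4 protein-coding genes of its inner part reached 1 FPKM in all libraries, with HLA-C at 102 to 120, which argues against loss of the whole region. Reads lost to alternative copies of the region in the reference are a candidate explanation. In the leukocyte receptor complex on chromosome 19, another region with alternative copies, 35 of 41 protein-coding genes (85.4%) were below 0.5 FPKM. How many of them PC9 cells would express was not examined, so that share alone says little. The ribosomal protein gene RPS9 there was set to be under 1 FPKM if this were the cause and above 100 if not. It stood between 0.513 and 1.57 and met neither bound, so by that rule the test left this explanation open. RPS9 lay far nearer the lower bound, and RPS10, a ribosomal protein gene outside both regions, stood at 1026 to 1512. Of other genes in the complex, NDUFA3 and TFPT were at 0 and PRPF31 at most 0.2075, while LENG8 stood at 0.923 to 2.36 and CNOT3 at 2.75 to 8.80. No other biological explanation was tested.

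The summed FPKM was lower in DTP, 0.847 times that of parental. A few abundant genes were not the whole cause, since the ratio was 0.862 without the 10 most abundant genes, with 0.837 to 0.889 between single libraries. Genes with transcripts under 1 kb differed from those over 2 kb by -0.353 on the log2 scale, against at most 0.066 between replicates. Because FPKM is scaled to transcript length and to mapped fragments, a lower sum largely implies a shift from short to long transcripts. The difference therefore shows where the sum was lower and cannot decide why. Short genes include many ribosomal and mitochondrial ones, so length and gene class cannot be separated here, and a biological difference stays open.

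The fall of proliferation genes was set against 2 technical explanations. After a trend on transcript length and GC was removed from each library, the G2/M median was -2.11, against -2.28 before, which argues against such a trend as the cause. A lower scale would lower all genes alike, but on the TPM scale the G2/M median lay -2.20 from that of all genes, which argues against a lower scale of all DTP values. As a hypothesis found and tested on the same data, lower proliferation of DTP cells stays open; cell numbers and other technical causes were not measured.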
